A study of Mus musculus with 2 samples.

How the data were processed

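Messenger RNA was measured in 2 libraries of C57BL/6 mouse peritoneal macrophages, 1 labelled Kdm2b knockout and 1 labelled wild type. Per the labels, the cells were collected 4 days after an injection of thioglycollate, a broth that draws macrophages into the peritoneal cavity, and were treated with 100 ng/ml of bacterial lipopolysaccharide (LPS). The time in LPS is given as 4 h in the sample characteristics and as 3 h in the treatment protocol, and which of these holds is not given in the sources used here. Per the labels' protocols, polyadenylated RNA was fragmented and copied with random primers into paired-end TruSeq libraries, which were sequenced on a HiSeq instrument. No strand marking is described there, so reads from a gene and from an antisense partner could not be told apart.

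The authors deposited 1 value per Ensembl gene and library in FPKM (fragments scaled to the length of the transcript and to the number of mapped fragments in the library), per the file headers. The submitters' processing notes name HISAT2 2.0.4, StringTie 1.3.0 and edgeR, together with the GRCm38.p4 and mm10 builds; the role of each tool, the annotation release and any filters are not given in the sources used here. FPKM divides by gene length and by library size, so a few very abundant genes, or a difference in RNA fragmentation between libraries, moves the values of all other genes. A gene-level FPKM value also cannot show which exons carried the reads.

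Gene symbols, coordinates, transcript lengths and GC content were taken from the GENCODE M21 annotation of GRCm38, with the longest transcript as the length of a gene. A symbol was found for 34267 of the listed IDs and none for 478. For 17 symbols with several IDs the FPKM values were summed. Sequencing depth was estimated from the FPKM values themselves: for genes with 1 annotated transcript, FPKM times length fell on whole multiples of 1 step. In the library labelled knockout the product was a whole multiple, within 0.02 of a fragment, for 92.5% of 1503 such genes with fewer than 20 fragments; in the wild-type library this held for 92.2% of 1440. The steps of 37.3 and 36.7 FPKM times bases correspond to about 26800000 and 27300000 fragments. For 714 low genes with several transcripts, 83.8% of the ratios between libraries lay within 0.1% of a ratio of small whole numbers (up to 6), against 0.1% of shifted ratios. Fragments per gene were estimated with these steps. Exact Clopper-Pearson 95% intervals of the ratio were computed from them, without a pseudocount. They cover counting error only, since PCR copies are not independent molecules, and for genes with several transcripts they depend on the length assumed.

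Each gene was compared by the log2 ratio of the library labelled knockout over the wild-type library, computed from FPKM + 1, which understates the change of low genes. A gene entered when its mean over both libraries reached 1 FPKM. A gene was counted as higher or lower by a fixed rule of size, at least 2-fold on this scale. With 1 library per group no test across samples was possible, and no p-value is given. Gene lists fixed in advance, 45 in all with 914 distinct genes, of which 7 were not found, covered pathways, protein complexes, cell type markers and RNA quality. A list with at least 5 genes past the floor was described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. Of the 39 such lists about 1.95 were to fall outside the central 95% by chance. The percentiles describe these libraries and not the genotypes.

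The comparison, the floors, the lists and the rule for named genes were set before the data were examined. The rule named Kdm2b and the cytokines Il6, Tnf, Il1b, Il12b, Il10 and Ifnb1. It also named the 10 highest and the 10 lowest log2 ratios among genes with a mean of at least 5 FPKM, leaving out provisional gene models, pseudogenes and immunoglobulin or T cell receptor segments. In each described list it named up to 4 genes with the largest ratios in either direction. Other genes named were chosen after their values were seen. The alternatives were a pseudocount of 0.1 or 5, scaling the libraries to a median log2 ratio of 0, to equal upper quartiles or to equal totals, a floor of 5 or none, fold thresholds of 1.5 and 4, and random lists matched on size alone. Removing the trend of the log2 ratio with transcript length and GC content (20 bins each) and keeping protein-coding genes only were added after the data were seen.

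The calculations were tested on simulated data for the same comparison and, for the random lists, on the measured log2 ratios. Among 9014 genes, of which 200 were given known changes, a 2-fold change was called in 7% of cases and a 4-fold change in 93%, and 0 of the unchanged genes were called; the simulation held counting error only, with no spread between animals. Of 40 random lists drawn from the measured ratios, 4 fell outside the central 95%, which is above the nominal share. When these lists were shifted by 0.3, 40 of 40 were found. A list of short genes under a simulated length trend moved from percentile 0 to 51.2 when the trend was removed. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.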

Results

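The data were the FPKM values of 2 RNA sequencing libraries from LPS-treated, thioglycollate-elicited mouse peritoneal macrophages, 1 labelled Kdm2b knockout and 1 labelled wild type. An estimated 26800000 fragments lay behind the library labelled knockout and 27300000 behind the wild-type library. In the first, 16185 genes were above 0 and 9196 reached 1 FPKM; in the second these were 16062 and 8820. The 10 most abundant genes held 21.03% and 19.7% of the FPKM sums. The most abundant gene was Fth1, the ferritin heavy chain, at 12660 FPKM in the library labelled knockout, and mt-Co1, a mitochondrial cytochrome oxidase subunit, at 10719 FPKM in the wild-type library. There were no replicates, so no difference could be set against the spread between animals, and every statement describes these libraries.

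Kdm2b, which encodes a histone demethylase of the variant Polycomb complex PRC1.1, was not lower in the library labelled knockout. Its value (ENSMUSG00000029475, chromosome 5, 122870665 to 122989823, GRCm38) was 0.326 FPKM there and 0.205 FPKM in the wild-type library, about 45 and 29 fragments, a log2 ratio of 0.14 on the FPKM + 1 scale. The 95% counting interval of the ratio ran from -0.05 to 1.38, so at this depth the libraries could not be told apart, and a loss of most of the transcript lay outside it. The annotation holds 20 transcripts of this gene, and the gene overlaps another annotated gene on the same strand. A gene-level value does not show a deleted exon when the rest of the transcript is kept. The value therefore showed no loss of the transcript and did not exclude a deletion of that kind, and each direction below is that of the library labelled knockout, not of a verified genotype.

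The libraries were close for most genes. Of 9039 genes past the floor, 78 were at least 2-fold higher and 92 at least 2-fold lower in the library labelled knockout, which is 1.88% in all. Here and below, fold counts use the FPKM + 1 scale, so a gene can be 2-fold apart in FPKM and go uncounted. The 95% counting interval excluded 0 for 169 of these 170. The log2 ratios had a median of 0.10 and an SD of 0.36. With the library labelled knockout scaled by 0.915, which moved the median from 0.10 to 0, the counts became 44 higher and 113 lower. The balance turned with equal totals (96 higher and 76 lower) and with a pseudocount of 0.1 (174 higher and 137 lower). The higher genes included 74 protein-coding genes and 7 collagen genes. The lower genes included 72 protein-coding genes, 6 immunoglobulin genes, 7 of the 22 measured chemokines and 1 collagen gene, Col23a1 (0.325 and 2.47 FPKM). Genes that overlap another annotated gene on the same strand made up 22.5% of the genes at least 2-fold apart and 22.6% of the others.

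The 10 lowest named genes ran from a log2 ratio of -2.87 to -1.54. Retnla, a marker of alternatively activated macrophages, stood at 0.499 FPKM in the library labelled knockout and 9.99 FPKM in the wild-type library (log2 ratio -2.87). Csf2, which encodes the growth factor GM-CSF, stood at 6.34 and 40.1 FPKM (log2 ratio -2.48), and the chemokine gene Ccl17 at 2.98 and 14.6 FPKM (log2 ratio -1.97). Spp1, which encodes osteopontin, was the most abundant of them, at 282 and 908 FPKM (log2 ratio -1.69). Tgtp1, an interferon-inducible GTPase with a near-identical neighbouring copy and therefore uncertain, had a log2 ratio of -1.69, and Ifitm6, of the interferon-induced transmembrane family, one of -1.64. The others were the organic cation transporter gene Slc22a4 (-2.35), the GTPase gene Rab12 (-1.87), the zinc finger gene Plagl2 (-1.57) and the class II gene H2-Eb1 (-1.54).

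The highest named genes reached about 4-fold on the FPKM + 1 scale, apart from a Y-linked gene. Emp1, a membrane protein gene, stood at 39.4 FPKM in the library labelled knockout and 9.39 FPKM in the wild-type library (log2 ratio 1.96). Col1a1, a chain of type I collagen, stood at 16.0 and 3.63 FPKM (1.87), and the matrix gene Fbln2 at 12.0 and 2.69 FPKM (1.82). Dusp4, a phosphatase of MAP kinases, had a log2 ratio of 1.81, and Mapk14, a MAP kinase active in LPS signalling, 1.53, from 47.4 and 15.8 FPKM. F7, coagulation factor VII, stood at 72.5 and 21.95 FPKM (1.68), Thbs1, thrombospondin, at 81.9 and 31.6 FPKM (1.35), Tbc1d23 at 21.5 and 6.50 FPKM (1.59), and Fosl1, an AP-1 subunit gene, at 8.17 and 2.73 FPKM (1.299). The Y-linked gene Eif2s3y was at 10.2 FPKM and was listed at 0 in the wild-type library. Of these 20 genes, 3 (Tgtp1, Spp1 and Mapk14) overlap another annotated gene on the same strand and 8 overlap one on either strand, and their values are uncertain for that reason.

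**Figure D1:**
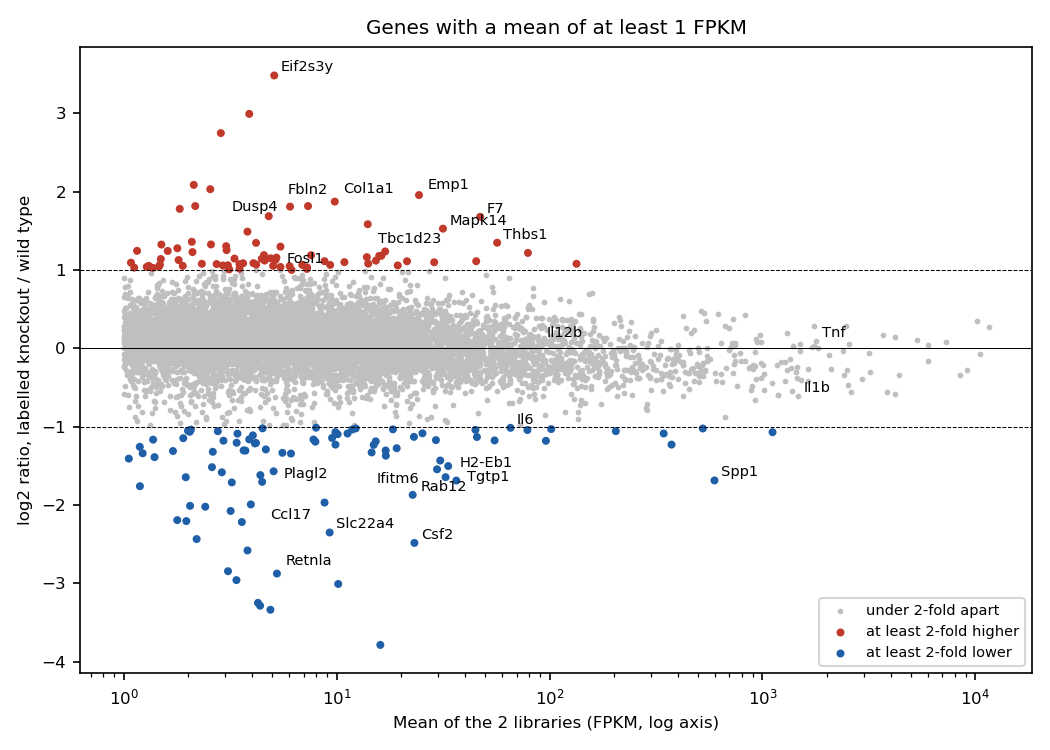
Each point is 1 of the 9039 genes past the floor, with its mean over both libraries in FPKM on a log axis and its log2 ratio of the library labelled knockout over wild type on the vertical axis. Dashed lines mark 2-fold: 78 genes lie on or above the upper line and 92 on or below the lower one, with Csf2 and Spp1 among the lower genes and Emp1 and Col1a1 among the higher.

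Inflammatory cytokine genes did not differ alike between the libraries. Il6, an acute-phase cytokine gene, was lower in the library labelled knockout, at 43.1 against 88.1 FPKM (log2 ratio -1.01). Il1b (1156 and 1768 FPKM, -0.61), Il1a (2111 and 3115 FPKM, -0.56) and the anti-inflammatory cytokine gene Il10 (5.47 and 9.82 FPKM, -0.74) were lower by less. Tnf stood at 1841 and 1725 FPKM (0.09) and Il12b, a subunit of interleukin-12 and interleukin-23, at 93.7 and 88.1 FPKM (0.09). Scaling to a median of 0 turned both of these to the other side of 0, at -0.03 for Tnf and -0.04 for Il12b. The interferon gene Ifnb1 stood at 23.1 and 33.8 FPKM (-0.53).

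Il6 (ENSMUSG00000025746, chromosome 5, 30013114 to 30019981) had a 95% counting interval of -1.10 to -0.96, from about 2707 and 5628 fragments. Csf2 (ENSMUSG00000018916, chromosome 11, 54247271 to 54249667) had one of -2.93 to -2.40, from about 136 and 874 fragments. Of the 26 measured genes of the inflammatory cytokine list, Csf2 and Il6 were the 2 at least 2-fold lower on the FPKM + 1 scale. None was 2-fold higher. At 1.5-fold, 5 were lower, with Osm (3.44 and 7.76 FPKM, -0.98) among them, and 4 were higher: Csf1, Lif, Tnfsf15 and Tgfb1. The list had a median of -0.16, at percentile 2.04 of matched random lists. At a floor of 5 FPKM it lay at percentile 6.15. With the length and GC trend removed the median was 0.09, at percentile 57.4, and Ifnb1 moved to -0.05, while Il6 stood at -0.86 and Csf2 at -2.04.

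Chemokine genes, which encode secreted attractants of leukocytes, were lower as a group in the library labelled knockout. Of 22 measured, 7 were at least 2-fold lower and 0 were 2-fold higher; at 1.5-fold, 12 were lower and 1, Cxcl3, was higher. Ccl17, Cxcl13 (17.0 and 49.9 FPKM, log2 ratio -1.50), Cxcl9 (9.07 and 25.0 FPKM, -1.37) and Ccl6 (223 and 525 FPKM, -1.23) had the largest differences, and the monocyte attractant Ccl2 stood at 719 and 1510 FPKM (-1.07). The neutrophil attractants Cxcl1 (346 and 324 FPKM) and Cxcl2 (228 and 247 FPKM) and the abundant Ccl3 (2368 and 2418 FPKM) were within 1.5-fold. The median of -0.59 lay under all 10000 matched random lists (percentile 0, random median -0.06). With the trend in length and GC removed it was -0.31, at percentile 0. Pf4, 1 of the 7, is also a platelet marker, and Ccl17 and Ccl22 also stood in the lists of alternative activation and, for Ccl22, dendritic cells.

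**Figure D2:**
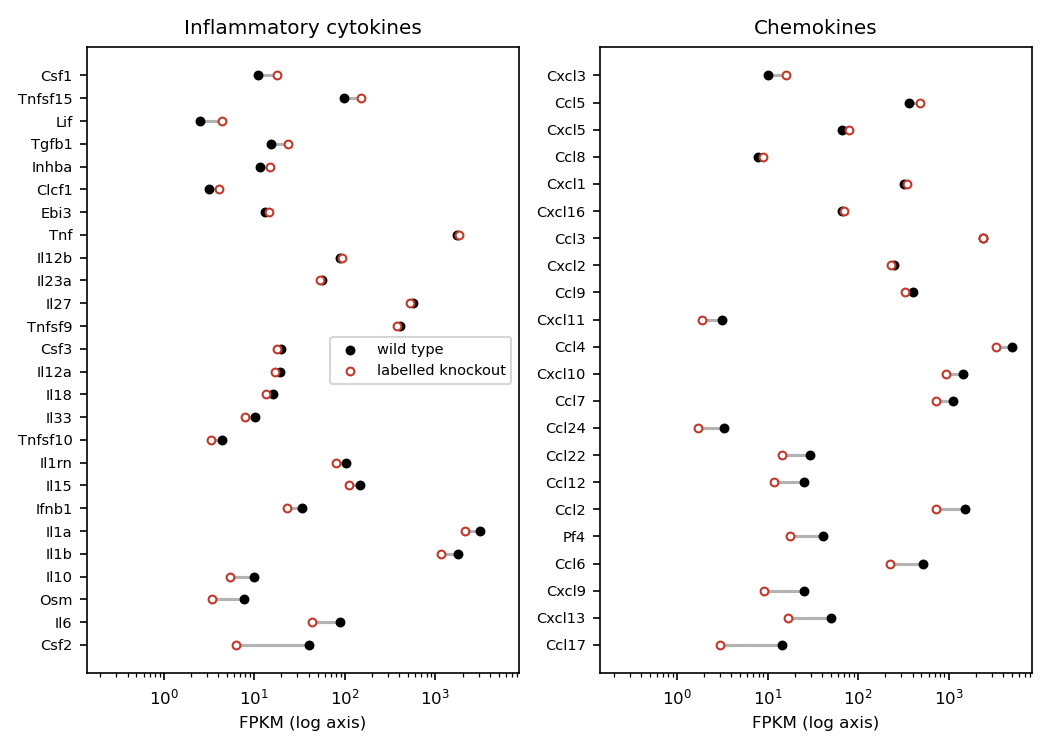
FPKM values of the measured genes of the cytokine and chemokine lists in both libraries, on a log axis, with a filled point for wild type, an open point for the library labelled knockout and genes ordered by log2 ratio. Csf2 has the lowest cytokine ratio (-2.48) and Ccl17 the lowest chemokine ratio (-1.97), while Tnf lies at 0.09.

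Lists of LPS-response genes had medians within the range of matched random lists. Both libraries were LPS-treated and no untreated library was used here, so these are levels and not responses. The 27 measured LPS primary-response genes had a median of -0.03 (percentile 65.0), with 12 genes above 0 and 15 below. None was 2-fold apart on the FPKM + 1 scale. Traf1, a signalling adaptor gene, was at 10.0 and 4.94 FPKM (0.89) and Ier3 at 67.6 and 123 FPKM (-0.85). The 21 LPS secondary-response genes had a median of -0.05 (percentile 44.8), with Cxcl9 and Il6 the 2 that were 2-fold lower. The 44 interferon-stimulated genes had a median of -0.10 (percentile 38.9) and 0 members 2-fold apart, with Ifi47 at 112 and 182 FPKM (-0.69) and Cxcl10 at 943 and 1427 FPKM (-0.60). With the length and GC trend removed the interferon-stimulated genes lay below the central 95%, at percentile 0.975.

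Genes of NF-kappaB, the transcription factor family activated by LPS, had a higher median in the library labelled knockout (21 genes, 0.30, percentile 99.99). On the FPKM + 1 scale 0 of them were 2-fold apart. The median of matched random lists was 0.02. With the length and GC trend removed the list median was 0.21 against 0.08 for random lists, at percentile 98.7, so the difference shrank. Nfkb1 (26.6 and 18.1 FPKM, log2 ratio 0.53) and Bcl3 (0.47) were higher. Feedback regulators went both ways: Tnfaip3 (42.4 and 60.04 FPKM, -0.49) and Tnip3 (3.99 and 8.27 FPKM, -0.89) were lower, and Zc3h12a (0.39), Nfkbie (0.38), Tnip1 (0.36) and Cyld (0.28) were higher. The 25 genes of the TLR4 receptor and its signal transduction had a median of 0.15 (percentile 85.2). The 2 of them at least 2-fold higher were Mapk14 and Tlr4, the LPS receptor gene itself, at 3.45 and 0.732 FPKM.

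Genes of MHC class II presentation, by which antigen is shown to helper T cells, were lower in the library labelled knockout (10 genes, median -0.41, percentile 0). H2-Eb1 (14.7 and 44.6 FPKM, log2 ratio -1.54) and H2-Aa (14.1 and 32.1 FPKM, -1.13) were at least 2-fold lower, and Cd74, the invariant chain (32.9 and 59.3 FPKM, -0.83), and H2-Ab1 (-0.71) at least 1.5-fold lower. Ciita, the regulator that switches on class II transcription, was under the floor and went the other way, at 1.36 and 0.537 FPKM (counting interval of the log2 ratio 0.97 to 1.71). Of 4 measured B cell markers, 2 were at least 2-fold lower there: Igkc, the kappa light chain constant region, stood at 1.47 and 18.9 FPKM (-3.01) and Ighm, the heavy chain of IgM, at 0.992 and 6.92 FPKM (-1.99). Of the other 2, Cd22 stood at 5.57 and 5.32 FPKM and Spib at 1.85 and 2.54 FPKM. Dendritic cell markers had a median of -0.27 (5 genes, percentile 5.96, or 1.44 with the length and GC trend removed), with Ccl22 at 14.6 and 29.2 FPKM. Of 3 measured T and NK cell markers, the kinase gene Lck stood at 2.63 and 6.36 FPKM (-1.02). It overlaps another annotated gene on the same strand. The others, Il7r (115 and 112 FPKM) and Thy1 (2.69 and 2.43 FPKM), were close. Cd3e, Cd3d and Cd3g were listed at 0 in both libraries, so Lck does not show a difference in T cells.

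Macrophage identity genes were close in both libraries, with a median of 0.00 (19 genes, percentile 73.1) and all 19 within 1.5-fold on the FPKM + 1 scale. MHC class I presentation genes had a median of 0.06 (19 genes, percentile 87.3). The 6 measured neutrophil markers had a median of 0.17 (percentile 57.4, or 99.4 with the length and GC trend removed), with Mmp9 at 2.83 and 1.54 FPKM. The rest of the 21 listed were under the floor, with Ly6g, Mpo and Retnlg at 0 in both libraries. The 6 therefore do not show a difference in neutrophils. Fewer than 5 members passed the floor for eosinophil and mast cell markers (Siglecf, 0.533 and 1.58 FPKM), for erythroid and platelet markers (Pf4, 17.6 and 40.9 FPKM) and for replication-dependent histones (Hist1h1c, 144 and 114 FPKM).

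The list of mesothelial and stromal markers had a higher median in the library labelled knockout than matched random lists, with members on both sides of 0 (19 genes, 12 above 0 and 7 below, median 0.35, percentile 99.99). The 5 at least 2-fold higher were Col1a1, Col1a2 (24.2 and 9.67 FPKM, log2 ratio 1.24), Col3a1 (22.9 and 9.54 FPKM, 1.18), the proteoglycan gene Bgn (21.3 and 9.27 FPKM, 1.12) and the matrix glycoprotein gene Sparc (182 and 85.6 FPKM, 1.08). The stromal proteoglycan genes Dcn, the most abundant of the list (251 and 248 FPKM, 0.02), and Lum (9.46 and 12.4 FPKM, -0.35) did not go with them. Mesothelial members of the list went both ways: Msln (-0.50), Krt19 (-0.31), Krt18 (-0.28), Upk1b (-0.19) and Krt8 (-0.18) were below 0, and Lrrn4 (0.55), Wt1 (0.44) and Upk3b (0.35) above. Matrix metalloproteinases and matrix genes had a median of 0.31 (19 genes, percentile 100), with Thbs1, fibronectin Fn1 (62.3 and 28.3 FPKM, 1.11), Timp3 (26.5 and 12.2 FPKM, 1.06) and Mmp2 at least 2-fold higher and Spp1 2-fold lower. At a floor of 5 FPKM this second list had a median of 0.07, at percentile 94.4.

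**Figure D3:**
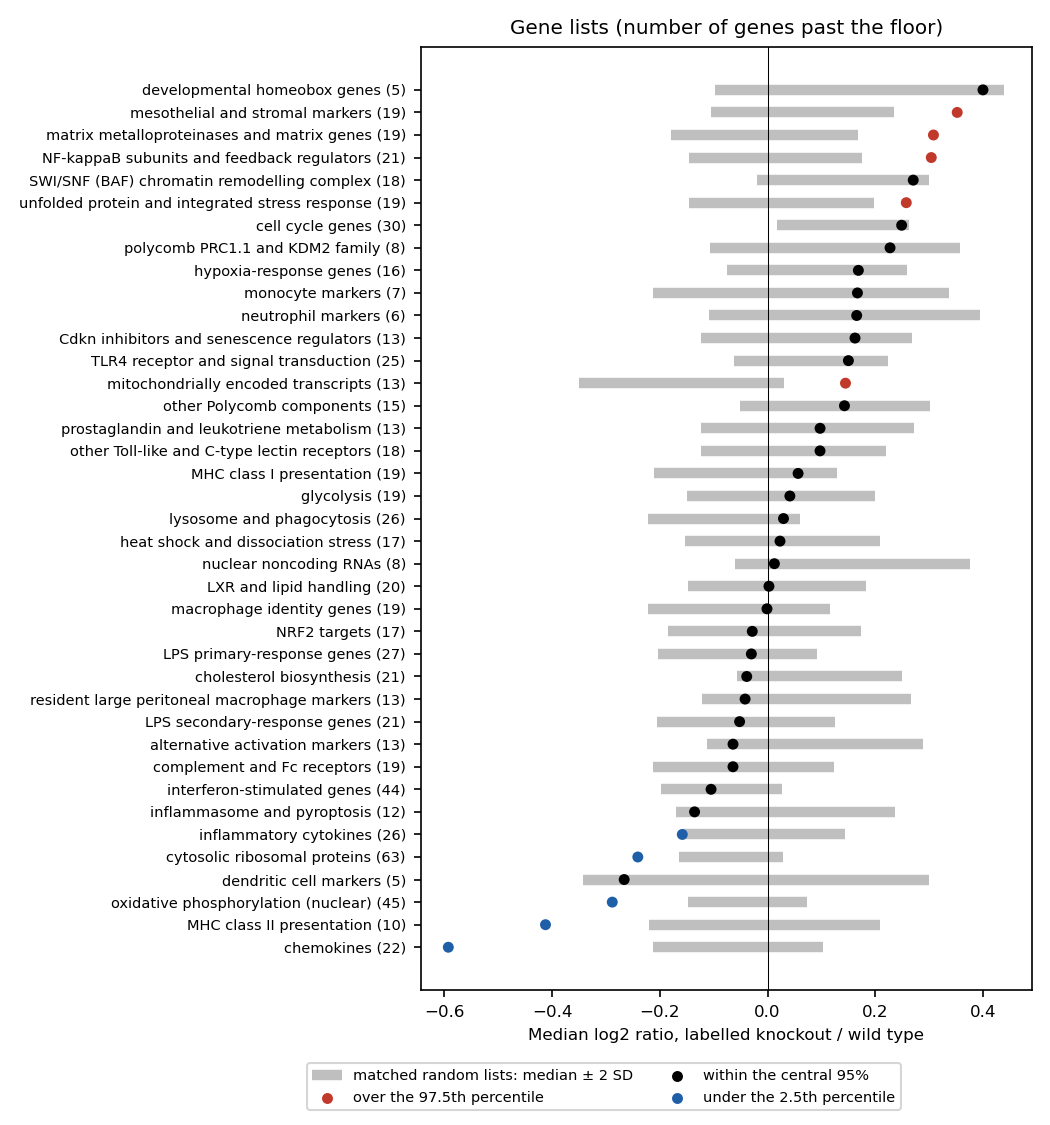
Median log2 ratio of the library labelled knockout over wild type for each of the 39 gene lists, with grey bars for the median ± 2 SD of matched random lists. The chemokines (-0.59) and MHC class II genes (-0.41) lie lowest, and the mesothelial and stromal markers (0.35) and matrix genes (0.31) lie above the central 95% of theirs.

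Genes of oxidative phosphorylation and of the cytosolic ribosome were lower by small amounts in the library labelled knockout, in nearly every member. Of 45 nuclear genes of oxidative phosphorylation, 41 were below 0 (median -0.29, percentile 0), with Uqcrh at 60.04 and 89.1 FPKM (-0.56) and Ndufa5 at 22.8 and 33.9 FPKM (-0.55), and all 45 within 1.5-fold. Of 63 ribosomal protein genes, whose reads can be shared with processed pseudogenes, 54 were below 0 (median -0.24, percentile 0.01), with Rpl34 at 23.9 and 33.0 FPKM (-0.45) and Rpl13a at 804 and 1054 FPKM (-0.39). The 13 mitochondrially encoded transcripts had a median of 0.14 (percentile 99.9, or 66.9 among random lists matched on size alone), with mt-Nd5 at 613 and 450 FPKM (0.45) and mt-Nd3 at 1097 and 1466 FPKM (-0.42). The log2 ratio went with transcript length over all genes: the median was -0.23 in the shortest 10% of genes (132 to 1200 bases) and 0.29 in the longest 10% (6251 to 123179 bases). By GC content it was 0.05 in the lowest 10% of genes and 0.18 in the highest 10%. With the trend in length and GC removed, the ribosomal protein genes had a median of 0.02 (percentile 6.95) the oxidative phosphorylation genes -0.05 (percentile 0.15) and the mitochondrially encoded transcripts 0.63 (percentile 100).

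**Figure D4:**
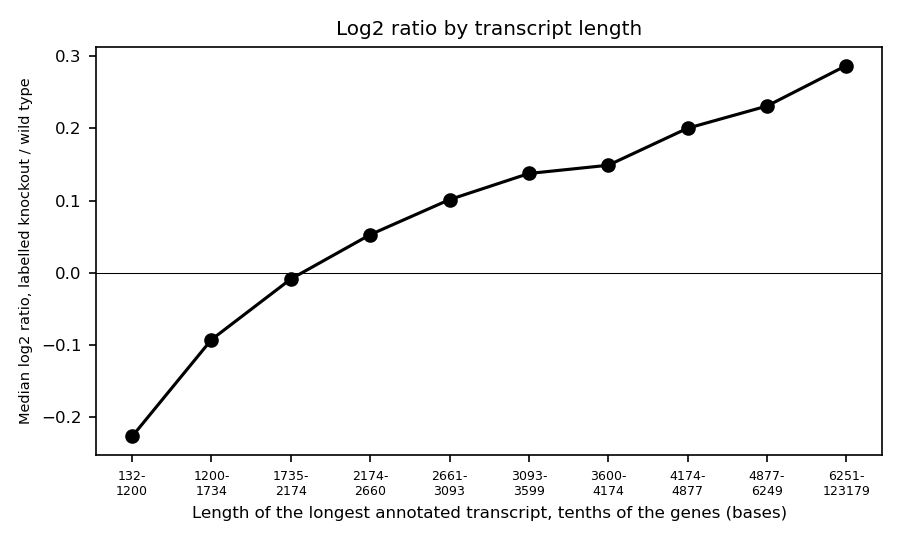
Median log2 ratio of the library labelled knockout over wild type in 10 groups of equal size of the genes past the floor, ordered by transcript length in bases. The median goes from -0.23 in the shortest genes to 0.29 in the longest.

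The list of the unfolded protein and integrated stress response had a higher median in the library labelled knockout than matched random lists (0.26, percentile 99.6). Of its 19 genes, 14 were above 0 and 5 below. On the FPKM + 1 scale 3 were at least 1.5-fold higher and 1 lower, and 0 were 2-fold apart. The cystine transporter gene Slc7a11 stood at 18.5 and 8.85 FPKM (log2 ratio 0.98), the stress sensor gene Sesn2 at 10.5 and 6.03 FPKM (0.71) and Herpud1 at 13.5 and 8.18 FPKM (0.66), whereas the endoplasmic reticulum chaperone gene Hspa5 was lower, at 73.7 and 113 FPKM (-0.61). Heat shock and dissociation stress genes lay within the range of random lists (17 genes, median 0.02, percentile 47.1), with Bag3 at 10.2 and 6.68 FPKM.

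The medians of lists of chromatin complexes lay within the central 95% of matched random lists in the reported setting. The 8 measured genes of the list of PRC1.1 and the KDM2 family had a median of 0.23 (percentile 81.7). None was 1.5-fold apart on the FPKM + 1 scale. Kdm2b itself and Kdm2a (0.940 and 1.01 FPKM) were under the floor and are not among the 8. Bcor stood at 8.70 and 5.54 FPKM (log2 ratio 0.57) and Ring1 at 2.61 and 1.75 FPKM (0.40). The 18 genes of the SWI/SNF chromatin remodelling complex had a median of 0.27 (percentile 95.7). In 2 of 11 settings the list lay above the central 95%, at up to percentile 98.8. With the length and GC trend removed its median was 0.14, at percentile 60.9. Of the SWI/SNF genes 14 were above 0 and 4 below, and on the FPKM + 1 scale 1 was at least 1.5-fold higher and 1 lower. Arid1a stood at 3.30 and 1.83 FPKM (0.61), Smarca4 at 8.92 and 5.75 FPKM (0.56) and Ss18 at 4.82 and 8.13 FPKM (-0.65). The nuclear noncoding RNA genes had a median of 0.01 (8 genes, percentile 10.9), with Neat1 at 4.95 and 1.69 FPKM (1.15) and Malat1 at 6.95 and 4.65 FPKM (0.49).

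Sex-linked transcripts separated the libraries. Xist, the RNA that coats an inactive X chromosome, stood at 0.00398 FPKM in the library labelled knockout, about 2 fragments, and at 8.55 FPKM in the wild-type library, about 4183 fragments. The Y-linked genes Ddx3y (5.72 FPKM), Kdm5d (0.592 FPKM) and Uty (0.574 FPKM) were measured in the library labelled knockout and were listed at 0 in the wild-type library. By these transcripts the library labelled knockout came from male cells and the wild-type library from female cells. Sex therefore differed along with the label in every comparison made here.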

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

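The trend removal and the protein-coding restriction were tests chosen after the results were seen; the other settings were planned. No paired analysis was possible because there was 1 library per group, and for the same reason no replicate could be left out. Chemokines, MHC class II and oxidative phosphorylation genes stayed below the central 95% of random lists, and stromal, NF-kappaB and stress response genes above it, in all 11 settings, the reported one included. The median of the chemokines (-0.59 as reported) was -0.45 with a pseudocount of 5, -0.72 with the median ratio set to 0, -0.50 with equal totals and -0.31 with the trend removed. The median of the inflammatory cytokines (-0.16) was -0.28, -0.0697 and 0.0858 under the last 3 of these, and that of the ribosomal proteins (-0.24) was 0.0152 with the trend removed, the only reversals of a median called outside random lists; the removal of a length trend by itself raises lists of short genes. The 78 higher genes became 174 and 14 with pseudocounts of 0.1 and 5, 44 with the median ratio set to 0, 35 at a floor of 5, and 425 and 5 at fold thresholds of 1.5 and 4. The 92 lower genes became 137 and 33 with pseudocounts of 0.1 and 5, 76 with equal totals (96 higher), 48 at a floor of 5, 253 and 18 at 1.5-fold and 4-fold, and 61 with the trend removed. The 10 lists outside random lists became 18 with the trend removed. Kdm2b had a log2 ratio of 0.48 with a pseudocount of 0.1. Of 106 values of named genes, 13 moved by more than the spread of genes of like expression with a pseudocount of 0.1, 26 with one of 5, 29 with the trend removed and 0 under the 3 scalings. Depth limits Kdm2b, with about 45 and 29 fragments, and not the abundant cytokines.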

Other observations

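The tests of a smaller macrophage share, of fibroblast-like cells, of fibroblast-like cells of unchanged make-up, of the spread of the mesothelial genes, and of the ribosomal protein and oxidative phosphorylation lists taken singly were chosen after the results were seen; the others were written before. The design sets 1 library against 1, so genotype, animal, sex of the animal and cell composition are confounded in every pattern, and no explanation by genotype was tested.

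As reported, cell cycle genes lay within the range of matched random lists (30 genes, median 0.25 against a random median of 0.14, percentile 96.8). In 5 of 11 settings they lay above it, at percentile 99.99 with the length and GC trend removed. Of them 7 were at least 1.5-fold higher in the library labelled knockout and 0 lower. Among them Bub1b, of the spindle checkpoint, stood at 11.6 and 5.81 FPKM, and Rrm2, a subunit of ribonucleotide reductase, at 5.18 and 2.49 FPKM, while the proliferation marker Mki67 stood at 9.77 and 10.8 FPKM. Markers of alternative activation went both ways (13 genes, median -0.06, percentile 7.70; with the trend removed, median -0.26, percentile 0): Retnla, Ccl17 and the arginase gene Arg1 (5.56 and 13.5 FPKM) were at least 2-fold lower and Fn1 was 2-fold higher. Complement and Fc receptor genes had a median of -0.06 (19 genes, percentile 40.7, or 0.16 with the trend removed), with the complement gene C4b at 7.99 and 4.37 FPKM and the Fc receptor gene Fcgr4 at 85.2 and 151 FPKM. Among hypoxia-response genes (16 genes, median 0.17, percentile 82.6), the vasodilator gene Adm was the 1 that was 2-fold lower, at 10.8 and 27.5 FPKM.

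The remaining lists lay within the range of matched random lists as reported, and 4 of them left it with the trend removed, as given beside each. Resident large peritoneal macrophage markers had a median of -0.04 (13 genes, percentile 13), monocyte markers 0.17 (7 genes, percentile 78.8, or 99.0 with the trend removed), glycolysis genes 0.04 (19 genes, percentile 59.8, or 1.74), cholesterol biosynthesis genes -0.04 (21 genes, percentile 5.24, or 0.05) and lysosome and phagocytosis genes 0.03 (26 genes, percentile 94.1). Medians were 0.14 for other Polycomb components (15 genes, percentile 57.0), 0.16 for cell cycle inhibitor and senescence genes (13 genes, percentile 82.9), 0.10 for other Toll-like and C-type lectin receptors (18 genes, percentile 72.0), -0.14 for inflammasome genes (12 genes, percentile 5.27), -0.03 for NRF2 targets (17 genes, percentile 40.8), 0.00 for LXR and lipid handling genes (20 genes, percentile 43.3) and 0.10 for prostaglandin and leukotriene genes (13 genes, percentile 60.2). Of 27 listed developmental homeobox genes, a family that Polycomb complexes silence in many cells, 5 passed the floor. These 5 had a median of 0.40 (percentile 96.5, or 99.9 with the trend removed). Over the 10 settings with a percentile, the list median ran from 0.08 to 0.74 and its percentile from 84.9 to 99.9. Hoxb4 stood at 3.02 and 1.62 FPKM, Hlx at 4.49 and 2.10 FPKM and Hoxb7, near the floor, at 1.28 and 0.729 FPKM.

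The first pattern is the lower level of chemokine genes in the library labelled knockout. A trend of the ratio with transcript length and GC content is excluded as the whole cause. With the trend removed the list kept a median of -0.31, against 0.06 for matched random lists, at percentile 0.0. A smaller share of macrophages would lower the macrophage identity genes as much, but their median lay 0.59 above that of the chemokines, against an SD of 0.115 for the difference of random lists. Genotype, animal, sex and other differences in cell composition stay open and were not tested.

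The second pattern is the lower level of ribosomal protein and oxidative phosphorylation genes, which are short. For the ribosomal proteins alone, the length and GC trend could account for the difference: with the trend removed they lay at percentile 6.95 and a median of 0.02. For oxidative phosphorylation genes the test could not decide whether the trend was the whole cause. With it removed they stayed at percentile 0.15, but their median went from -0.29 to -0.05, against 0.06 for random lists. The percentile alone does not settle it, since 18 of the 39 lists then lay outside random lists, against 10 as reported. The removal also took the longest annotated transcript as the length of a gene. The 108 genes of both lists jointly went from -0.25 to -0.02, at percentile 0.04. A trend with length may come from RNA fragmentation or library preparation, which these data do not separate from biology.

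The third pattern is the higher median of the mesothelial and stromal markers. With the length and GC trend removed the list kept a median of 0.29, against 0.10 for matched random lists, at percentile 99.9. As reported these medians were 0.35 and 0.06, so the trend as estimated here took away only part of the difference. The test does not exclude the trend as the whole cause. With it removed 18 of the 39 lists lay outside random lists, and the longest annotated transcript was taken as the length of a gene. The mesothelial genes did not show more mesothelial cells, but such cells are not excluded as a source. The 13 measured mesothelial genes had a median of -0.18 at percentile 0.34 (5 above 0 and 8 below). Of the 16 listed, 11 are members of the stromal list itself, so the medians compared share genes. The mesothelial median lay 0.535 below that of the stromal list, against an SD of 0.446 between the mesothelial genes. With the trend removed (percentile 1.43) the gap of 0.357 was within their SD of 0.421. More fibroblast-like cells, or more matrix production by them, may be the source: 26 other fibroblast genes, 2 of the 34 listed being in the fixed lists and 24 reaching 1 FPKM in the wild-type library too, had a median of 0.57 at percentile 100, with 23 above 0. The 5 fibroblast genes most abundant in the wild-type library were Dcn (251 and 248 FPKM, 0.02), Sparc (1.08), Acta2 (113 and 74.9 FPKM, 0.59), Igfbp7 (57.7 and 61.1 FPKM, -0.08) and Cnn2 (0.06). They spanned 1.16 in log2 ratio, at percentile 91.2 of matched random sets. The counting intervals of Dcn (-0.01 to 0.04), Acta2 (0.54 to 0.65) and Sparc (1.04 to 1.14) lay apart, while those of Igfbp7 and Cnn2 overlapped that of Dcn. Whether such cells kept their make-up stays open: random sets of unrelated genes do not give the spread within 1 cell type, and the intervals cover counting error only.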
